A study of Mus musculus with 14 samples.

How the data were processed

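Gene expression was measured by RNA sequencing of mouse placenta at E13.5 and E14.5, in Adar1f/f controls and in the Adar1 knockout that the labels call Adar1PKO (PKO here). Per the labels and the series description, paired-end reads from an MGI platform were quality-filtered with Trim Galore 0.6.10 and aligned to the mm39 genome with STAR 2.7.9a by the authors. The submitters' processing notes also name R 4.4.1, edgeR 4.2.1 and DESeq2 1.44.0 without saying what each was used for. The counting tool, its strand setting and the gene annotation are not given in the sources used here.

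The deposited count table held 1 whole-number read count per gene and sample for 54096 genes, with a symbol, an Entrez identifier and a gene name, and with no scaling visible in the counts. The same table held fold values, which per the file headers and the values are linear ratios of knockout to control within each stage, made by the authors with a tool they do not name. It also held the authors' p-value for each gene and stage, without a statement on whether it was adjusted. A second deposited table held FPKM values (fragments scaled for gene length and library size) computed by the authors for 16336 genes, all of them present in the count table. A further 28 deposited columns with a value per sample carried a heading that does not say how they were made, and they were not used. The counts were analysed, the FPKM values served in alternatives, and the deposited fold and p-value columns served for a comparison.

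Columns named WT and KO were assigned to the control and PKO groups of their stage. Each PKO title shares the start of its number code with 1 control title of its stage (3 pairs at E13.5 and 4 at E14.5). The columns carry no code that links them to single sample titles, so this pairing could not be used and columns were matched to groups and are numbered as in the table. All 14 libraries were used: 3 control and 3 PKO at E13.5, 4 control and 4 PKO at E14.5. Total counts per library ran from 31093671 to 34558475. A count of 0 was given a limit of 3 counts per library, or over a group where said, which covers counting error only. Pairs of libraries within a group differed by a chi-square per degree of freedom of at least 30.3, so no pair was a copy of another.

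The main test was the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, on counts scaled by TMM. Genes were kept by filterByExpr with its defaults (minimum count 10, minimum total count 15, minimum proportion 0.7), which left 19504. The 4 groups were fitted together as group means, with robust estimation. The contrasts were PKO against control at E13.5 and at E14.5, the difference between these effects, and control at E14.5 against control at E13.5. Adjusted p-values are Benjamini-Hochberg over all tested genes, and a gene was called at an adjusted p under 0.05. CPM values are TMM-scaled, and log2 CPM for list scores used a prior count of 2.

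Gene lists for 37 pathways and cell types were tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted over the lists, in the 3 PKO contrasts and, in addition to the plan, in the control contrast. For each list the members called over all genes were counted, and also those called when adjusted over the list alone. Several genes stand in more than 1 list, among them Zbp1, Bbc3, Gdf15 and Slc7a11, and placental cells express members of lists named for other cell types. The lists cover interferon and double-stranded RNA responses, stress and cell death pathways, trophoblast subtypes, endothelium, mesenchyme, decidua, blood and immune cells, yolk sac, transport, hormones, metabolism, imprinted and sex-linked genes. Every list's result at E14.5 is given once.

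Genes were named by a rule. It took Adar, up to 8 higher and 8 lower called genes of largest fold change with a mean of at least 5 CPM, no overlap between the groups and a symbol of a known gene, and up to 3 called genes per direction of each list. Where a list had no called gene, its 2 members with the highest level could be named. Tpbpa, Atf4, Asns, Hspa5 and Eif2ak2, genes named at E13.5 where none was called, and members of gene families stand outside the rule and were chosen after their values were seen. The groups, the tests, the lists, the rule and the alternatives, except 2 added later, were set before the data were examined.

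Alternatives were edgeR with relative log expression scaling, no filter on low counts, a minimum mean of 5 CPM, a log2 fold change of at least 1, and DESeq2 1.42.0. Others were limma on log2 of FPKM plus 1 or plus 0.1 (genes with at least 0.5 in 3 libraries), the libraries of a stage alone, and a covariate for Y-linked transcripts. Each library was left out in turn. For the lists, an estimated inter-gene correlation and fry were used. The 2 added later were a covariate for the yolk sac list and, for the lists, an estimated correlation without PKO library 3 of E13.5. Differences between 2 groups of list scores were tested by exact permutation, and correlations over 14 libraries with 100000 permutations, both two-sided. At E14.5 the median log2 difference of all tested genes between PKO and control was 0.26 with counts per total, 0.06 with TMM and 0.04 with relative log expression, so TMM moved it by -0.20. The fold changes of the main test are given after TMM scaling.

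The steps were tested on simulated data with 200 changed genes among 19504. In a design like that of E13.5, edgeR recovered 7.46% of genes changed 1.5-fold, 53.7% of those changed 2-fold and 87.9% of those changed 4-fold, with 2 false calls, and DESeq2 34.3%, 74.6% and 93.9% with 61 false calls. In a design like that of E14.5, edgeR recovered 20.9%, 71.6% and 83.3% with 5 false calls, and DESeq2 31.3%, 85.1% and 90.9% with 36. Limma made 3 and 8 false calls, and camera called 0 of the fixed lists. The simulated genes varied independently of each other, so this could not show how camera behaves where genes are correlated.

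In the deposited p-values, 341 genes at E13.5 and 3192 at E14.5 were under 0.05, and 0 were under 0.05 after Benjamini-Hochberg adjustment at either stage. Of the 2566 genes called here at E14.5, 1909 had a deposited p-value under 0.05, and 100% had a deposited fold of the same sign. Gene positions are from the GENCODE annotation of GRCm39, the same build as mm39 but not necessarily the authors' release, and 149 of 150 named genes matched 1 annotated gene by symbol. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.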

Results

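RNA from mouse placenta was sequenced in 14 libraries, and the reads were deposited as counts for 54096 genes. Control placentas carried floxed Adar1 alleles (Adar1f/f), and the others came from an Adar1 knockout named Adar1PKO in the labels (PKO here). ADAR1, encoded by Adar, is an enzyme that converts adenosine to inosine in double-stranded RNA. There were 3 control and 3 PKO libraries at E13.5, and 4 control and 4 PKO libraries at E14.5 (embryonic days). Total counts per library ran from 31093671 to 34315904 at E13.5 and from 33938194 to 34558475 at E14.5. A gene with a count of 0 could thus have a level of up to 0.0868 to 0.0965 CPM (counts relative to the library's total), depending on the library (3 counts, covering counting error only). The labels speak of 3 biological replicates, while 14 samples are listed. Each PKO title shares the start of its number code with 1 control title of its stage, so the titles pair the placentas without saying what a pair shares. The data columns carry no such code, and all tests and permutations treat the libraries as unpaired. Each listed sample was taken as 1 replicate. The 4 groups share 1 fit, so the edgeR and camera p-values and the standard errors carry the spread within all 4 groups. A wide spread at E13.5 thus also weakens the tests at E14.5. Levels are CPM scaled by trimmed mean of M-values (TMM), given as mean ± SD. Fold changes are log2 of PKO over control with a standard error (SE) derived from the test. It is the absolute log2 fold change over the square root of edgeR's F statistic, so it does not describe the libraries of 1 stage alone.

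The first comparison asked whether transcript levels of the targeted gene itself differed. Adar (Entrez identifier 56417, GRCm39 chromosome 3, 89622329 to 89660753, 15 exons in its canonical transcript) was measured at 64.1 ± 13.1 CPM in control and 65.4 ± 6.99 CPM in PKO placentas at E13.5 (n = 3 each). At E14.5 the levels were 69.3 ± 14.6 CPM in control and 72.8 ± 11.5 CPM in PKO placentas (n = 4 each). The control libraries had 62.1, 78.0 and 52.1 CPM at E13.5 and 57.8, 58.3, 88.6 and 72.5 CPM at E14.5. The PKO libraries had 70.2, 57.4 and 68.6 CPM at E13.5 and 71.6, 58.7, 86.6 and 74.2 CPM at E14.5. The log2 fold change was 0.03 (SE 0.19, edgeR adjusted p = 0.997) at E13.5 and 0.07 (SE 0.17, edgeR adjusted p = 0.816) at E14.5, smaller than the spread between libraries. Its sign turned at E13.5 without control 3 (to -0.10), PKO 1 (-0.02) or PKO 3 (-0.01), and at E14.5 without control 1 (-0.01), control 2 (0.00) or PKO 3 (-0.04). The counts cover all exons of the gene and all cells of the tissue, so they check nothing about the deletion.

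The comparison of PKO with control placentas at E14.5 asked which transcripts accompany the Adar1 knockout, with innate immune and integrated stress responses as the subject of the study's title. PKO placentas had higher levels of most interferon-stimulated genes, of 3 interferon genes that had no read in any control, and of 18 of 39 targets of the integrated stress response. They had lower levels of most genes of the spongiotrophoblast, sinusoidal and canal giant cell and endoplasmic reticulum (ER) folding lists. Camera called 17 of the 37 lists with a preset correlation between genes, and 0 of these passed with an estimated one. By fry, 12 of the 17 passed. Without the E13.5 library labelled PKO 3 (chosen after seeing the data), 3 of the 17 passed with an estimated correlation. These were interferon-stimulated genes, double-stranded RNA sensors, and guanylate-binding and immunity-related GTPases (camera adjusted p = 0.00972, 0.0380 and 0.0324). By edgeR, 2566 of 19504 tested genes changed (adjusted p under 0.05), 1244 higher and 1322 lower in PKO. Of these, 412 were higher and 577 lower by a log2 fold change of at least 1. The count fell to 1044, 1065 and 1030 without control libraries 1, 3 and 4 of this stage, and to 693, 1301 and 1488 without PKO libraries 1, 3 and 4.

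Interferon-stimulated genes, the transcripts that interferon signalling induces, rose in PKO placentas at E14.5. Of 48 tested members, 44 were higher and 0 lower by edgeR over all genes, and 47 were higher adjusted over the list alone. The median log2 fold change was 1.69, and camera called the list higher (adjusted p = 1.0e-24 with the preset correlation; adjusted p = 0.328 with an estimated correlation). Mx2 (Entrez identifier 17858, chromosome 16, 97336508 to 97362100), an antiviral dynamin-like GTPase, went from 4.30 ± 0.613 CPM in control to 96.1 ± 15.2 CPM in PKO placentas (n = 4 each). Its log2 fold change of 4.48 (SE 0.84, edgeR adjusted p = 0.0126) was the largest increase among named genes with a mean of at least 5 CPM and no overlap between the groups. Without the library labelled PKO 3 of E13.5, which shares the fit, the SE of Mx2 at E14.5 was 0.38. Its relative Mx1 rose by 3.86 (SE 0.78), and the 2'-5' oligoadenylate synthetase-like gene Oasl1 by 3.30 (SE 0.56). Ifit3, Ifit3b and Ifit2, which encode antiviral proteins with tetratricopeptide repeats, rose by 3.03, 3.02 and 2.99. Reads of the near-identical Ifit3 and Ifit3b, and of the Oas1 genes, cannot be assigned with certainty to 1 copy.

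Sensors and effectors of double-stranded RNA included 14 higher and 0 lower of 24 tested members over all genes (17 higher and 1 lower adjusted over the list alone). The median was 1.18 (camera adjusted p = 4.1e-08; adjusted p = 0.328 with an estimated correlation). The calls included Oas1g, an activator of RNase L, at 2.64 (SE 0.45), and Zbp1, a sensor of left-handed nucleic acid that can trigger necroptosis, at 2.87 (SE 0.59). Zbp1 went from 5.52 ± 1.63 to 40.4 ± 11.4 CPM (n = 4 each). Eif2ak2, which encodes the translation-blocking kinase PKR, was at 43.5 ± 3.07 CPM in control and 80.3 ± 7.52 CPM in PKO placentas (log2 fold change 0.88, SE 0.28). Its edgeR adjusted p of 0.0532 missed the threshold, and the gene was chosen after its values were seen. Without the library labelled PKO 3 of E13.5, an omission chosen after seeing the data, the edgeR adjusted p of Eif2ak2 was 0.0173. DESeq2 called it.

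Interferon genes themselves were detected in PKO placentas at E14.5. Ifnb1, which encodes interferon beta (chromosome 4, 88440262 to 88441011), had 20 to 29 counts in each of the 4 PKO libraries and 0 in the 4 controls. Ifnl2 and Ifnl3, which encode type III interferons and lie side by side on chromosome 7, had 32 to 58 and 16 to 61 counts per PKO library and 0 in the controls. Against a floor of 3 counts over the control group, Ifnb1 was at least 30.5-fold, Ifnl2 at least 52.3-fold and Ifnl3 at least 37.2-fold higher. These were the 3 calls among 11 tested interferon ligand and receptor genes, with 0 lower (4 higher and 1 lower adjusted over the list alone). The list median was 0.31, the same with the 3 genes at their bounds (camera adjusted p = 0.0342; adjusted p = 0.444 with an estimated correlation). The Ifnb1 call was lost in 5 of the 14 omissions of 1 library (edgeR adjusted p up to 0.0647, without PKO 1) and that of Ifnl3 in 9 (up to 0.0744, without control 3). That of Ifnl2 was kept in all 14 (up to 0.0474, without PKO 1). Camera lost the list without control 4 (adjusted p = 0.0658).

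Guanylate-binding proteins and immunity-related GTPases, which interferon induces against intracellular pathogens, had 13 higher and 0 lower of 16 tested members (15 higher adjusted over the list alone). Their median was 1.61 (camera adjusted p = 2.6e-10; adjusted p = 0.328 with an estimated correlation). Gbp3 rose by 2.58 (SE 0.47) and Igtp by 2.09 (SE 0.40), and Gbp copies share sequence, so their single values are uncertain. In the MHC class I list, 3 of 18 members were higher and 0 lower over all genes and adjusted over the list alone (median 0.60; camera adjusted p = 0.00134; adjusted p = 0.560 with an estimated correlation). Tap1, a subunit of the peptide transporter of antigen presentation, rose by 1.17 (SE 0.24). Inflammatory cytokines and NF-kB targets had 5 higher and 0 lower of 23 members (7 higher adjusted over the list alone; median 0.59; camera adjusted p = 0.00912; adjusted p = 0.659 with an estimated correlation), and the median was 0.95 without control 4. Among them were the cytokine gene Tnf at 1.78 (SE 0.40) and the NF-kB subunit gene Relb at 1.84 (SE 0.43), whose calls were lost in 3 and 4 of the 14 omissions of 1 library (edgeR adjusted p up to 0.0538 without PKO 1 and 0.0581 without control 1).

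Targets of the integrated stress response, the programme that follows phosphorylation of the initiation factor eIF2 alpha, had 18 higher and 1 lower of 39 tested members at E14.5 (21 higher and 3 lower adjusted over the list alone). The median was 0.64 (camera adjusted p = 8.5e-07; adjusted p = 0.373 with an estimated correlation). Trib3 (chromosome 2, 152179337 to 152191958), a pseudokinase gene induced by ATF4 and CHOP, went from 19.9 ± 4.34 CPM in control to 112 ± 14.7 CPM in PKO placentas (n = 4 each; log2 fold change 2.50, SE 0.45, edgeR adjusted p = 0.0118). Asns, which encodes asparagine synthetase, rose by 1.46 (SE 0.30), and Atf4, which encodes the central transcription factor of the response, by 0.57 (SE 0.16). Both were named after their values were seen. The Atf4 call was lost in 8 of the 14 omissions of 1 library (edgeR adjusted p up to 0.104, without PKO 1). The stress-induced cytokine gene Gdf15 (1.56) and the cystine transporter gene Slc7a11 (1.83) were also called higher, and their calls were lost in 11 and 3 of these omissions (edgeR adjusted p up to 0.110 without control 4 and 0.0551 without control 3). Pycr1, a proline synthesis gene, was the lower member at -0.68, lost without control 1 or PKO 1 (edgeR adjusted p up to 0.0594).

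Chaperones and other ER folding genes moved the other way. Of 18 tested members, 14 were lower and 0 higher in PKO at E14.5 (17 lower adjusted over the list alone), with a median of -1.16 (camera adjusted p = 7.6e-13; adjusted p = 0.328 with an estimated correlation). The calcium-binding chaperone gene Calr (chromosome 8, 85567946 to 85573667) fell from 4450.1 ± 797 to 1593 ± 164 CPM (n = 4 each; log2 fold change -1.48, SE 0.29, edgeR adjusted p = 0.0133). Creld2, a secreted ER stress-induced gene, fell by 1.60 (SE 0.34). Hspa5, which encodes the ER chaperone BiP and was named after its values were seen, fell by 1.10 (SE 0.21). The calls for Calr, Creld2 and Hspa5 were kept in all 14 omissions of 1 library, but close to the threshold (edgeR adjusted p up to 0.0480, 0.0490 and 0.0474, without PKO 1).

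Cell death and damage genes were among the higher ones. The programmed cell death list had 8 higher and 0 lower of 23 members at E14.5 (9 higher adjusted over the list alone; median 0.51; camera adjusted p = 1.5e-05; adjusted p = 0.357 with an estimated correlation). Beside Zbp1 it held the proapoptotic p53 target Bbc3 at 1.88 (SE 0.42) and Mlkl, the executioner of necroptosis, at 1.04 (SE 0.25). The p53 target list had 6 higher and 0 lower of 17 members (7 higher adjusted over the list alone; median 0.63; camera adjusted p = 6.5e-05; adjusted p = 0.373 with an estimated correlation). The immediate early and heat shock list had 6 higher and 0 lower of 15 members (8 higher adjusted over the list alone; median 0.67; camera adjusted p = 0.00560; adjusted p = 0.659 with an estimated correlation). Its growth-factor-responsive gene Egr1 rose by 2.94 (SE 0.50) and the orphan receptor gene Nr4a1 by 1.92 (SE 0.40). In the oxidative stress list 1 of 15 members was higher, Slc7a11, with 1 also adjusted over the list alone (median 0.18; camera adjusted p = 0.239). The calls for Bbc3 and Mlkl were lost in 3 and 5 of the 14 omissions of 1 library, with edgeR adjusted p up to 0.0530 without PKO 1 and 0.0653 without control 1.

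**Figure D1:**
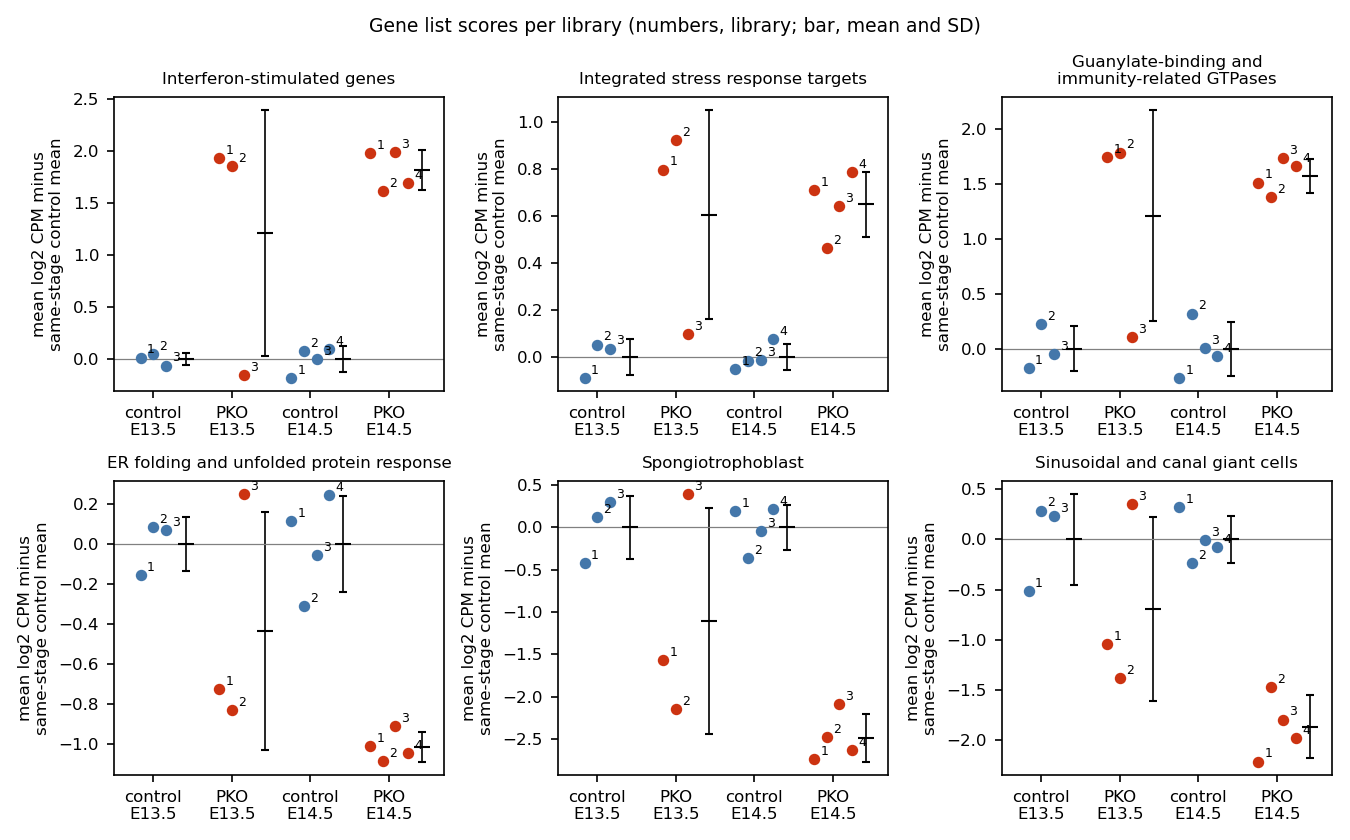
Mean log2 CPM of 6 gene lists in each library, minus the mean of the controls of the same stage; points are libraries with their numbers, and the black bar to the right of each group is its mean and SD. On the interferon-stimulated list the 4 PKO libraries at E14.5 lay between 1.61 and 1.99, and at E13.5 the PKO libraries lay at 1.93, 1.85 and -0.15.

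Spongiotrophoblast transcripts, from the hormone-secreting layer between labyrinth and decidua, fell most among the lists that camera called at E14.5. Of 19 tested members, 12 were lower and 0 higher, over all genes and adjusted over the list alone, with a median of -2.90 (camera adjusted p = 6.8e-12; adjusted p = 0.328 with an estimated correlation). Tpbpa (chromosome 13, 61086306 to 61089798), the classical marker of this layer and named after its values were seen, fell from 17953 ± 4358 to 1259 ± 331 CPM (n = 4 each; log2 fold change -3.83, SE 0.70, edgeR adjusted p = 0.0118). Prl8a8 (chromosome 13, 27690951 to 27697200), of the placental prolactin family, fell from 2735 ± 749.8 to 95.4 ± 22.6 CPM (n = 4 each; log2 fold change -4.84, SE 0.88). Ceacam12 fell by 4.31 (SE 0.78). Flt1, which encodes a receptor of vascular endothelial growth factor that also exists in a soluble form, fell by 1.89 (SE 0.36). It was the 1 lower gene, over all genes and adjusted over the list alone, of 14 angiogenic factors, of which 0 were higher (median 0.15; camera adjusted p = 0.677). Prl3a1 fell by 4.55 (SE 1.04), a call lost without PKO 1 (edgeR adjusted p = 0.0620). Prl, Psg and Ceacam copies share sequence, so their single values are uncertain.

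Some giant cell genes were lower as well. Sinusoidal and canal giant cell genes, from the cells that line the maternal blood spaces, had 7 lower and 0 higher of 12 members (9 lower adjusted over the list alone; median -1.39; camera adjusted p = 8.5e-07; adjusted p = 0.328 with an estimated correlation). The placental cathepsin gene Ctsm fell by 4.11 (SE 0.78) and its relative Cts3 fell by 3.92 (SE 0.76). Tpbpb, a relative of the spongiotrophoblast marker Tpbpa that also stands in this list, fell by 4.15 (SE 0.77). Its fall cannot be credited to giant cells alone. Cathepsin copies share sequence too. Parietal giant cell genes had 3 lower and 0 higher of 12, over all genes and adjusted over the list alone (median -0.65; camera adjusted p = 0.0576). Among them Prl2c5, a proliferin gene, fell by 1.77 (SE 0.34). Glycogen trophoblast genes had 3 lower and 0 higher of 12 (3 lower and 1 higher adjusted over the list alone; median -0.08; camera adjusted p = 0.198). The connexin gene Gjb3 fell by 1.13 (SE 0.23), while Aldh1a3, a retinoic acid synthesis gene, at -2.87, and Pcdh12, a protocadherin gene, at -1.05, lost their calls in 2 and 7 of the 14 omissions of 1 library (edgeR adjusted p up to 0.0593 and 0.0865, without PKO 1).

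Among called genes with a mean of at least 5 CPM, no overlap between the groups and a symbol of a known gene, the largest fold changes at E14.5 were ranked, 8 per direction. The interferon genes Ifnb1, Ifnl2 and Ifnl3 lay below that level and were not ranked. On the higher side were Mx2, Mx1, Oasl1, Ifit3, Ifit3b, Ifit2, Egr1 and Zbp1. On the lower side were Ceacam14 (-5.52, SE 1.03), Cabp7 (-5.40, SE 0.95), Prl8a8, Neurog2 (-4.76, SE 0.97), Psg26 (-4.68, SE 0.94), Prl3a1, Ceacam12 and Tpbpb. Cabp7 encodes a calcium-binding protein and Neurog2 a proneural transcription factor. The Neurog2 call was lost without PKO 1 (edgeR adjusted p = 0.0504).

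**Figure D2:**
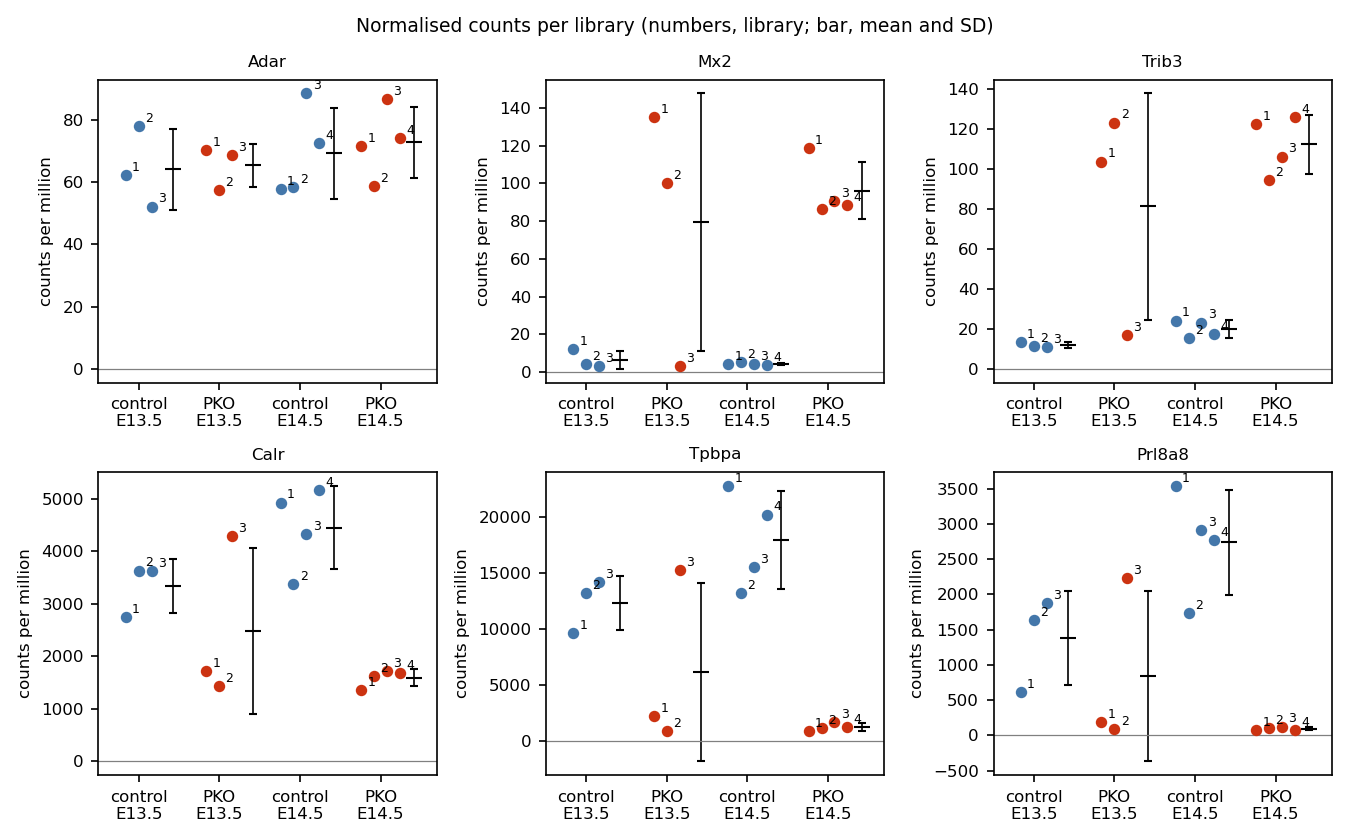
TMM-scaled CPM of 6 genes in each library; points are libraries with their numbers, and the black bar to the right of each group is its mean and SD. Adar overlapped between the genotypes, while at E14.5 the PKO libraries lay above the controls for Trib3 and below them for Calr and Tpbpa. Mx2 and Prl8a8 were selected for groups without overlap.

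Labyrinth and chorion lists showed smaller or mixed changes at E14.5. Syncytiotrophoblast layer II had 0 of 8 members called over all genes (3 higher adjusted over the list alone), a median of 0.49 and all 8 values above 0 (camera adjusted p = 0.0121; adjusted p = 0.517 with an estimated correlation). Syncytiotrophoblast layer I had 2 higher and 1 lower of 8 (2 higher and 2 lower adjusted over the list alone; median 0.06; camera adjusted p = 0.786). The higher ones were the transferrin receptor gene Tfrc (0.71) and the monocarboxylate transporter gene Slc16a1 (0.64), and the lower one the leptin receptor gene Lepr (-1.42). Labyrinth and chorion progenitor genes had 3 lower and 0 higher of 15 (4 higher and 4 lower adjusted over the list alone; median 0.16; camera adjusted p = 0.677). The lower ones were the trophoblast transcription factor genes Esrrb (-1.22), Tfap2c (-0.56) and Tead4 (-0.55). The calls for these 6 genes were lost in 3 to 6 of the 14 omissions of 1 library (edgeR adjusted p up to 0.0824, for Tead4 without control 4).

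Lists for other cells of the placenta held few calls. Fetal endothelium had 4 higher and 0 lower of 17 members, over all genes and adjusted over the list alone (median 0.45; camera adjusted p = 0.0477; adjusted p = 0.754 with an estimated correlation). Its call by camera was lost without control 2, control 4, PKO 1, PKO 3 or PKO 4 of this stage and without any PKO library of E13.5 (adjusted p of 0.0519 to 0.140), with a median of 0.25 without PKO 4. The higher genes included the apelin receptor gene Aplnr (1.00), whose groups overlapped and whose call was lost in 12 of the 14 omissions of 1 library (edgeR adjusted p up to 0.118, without PKO 4). Mesenchyme and pericytes had 2 lower and 0 higher of 14, over all genes and adjusted over the list alone (median -0.00; camera adjusted p = 0.690). The growth factor receptor gene Pdgfra fell by 0.94 (SE 0.20). Maternal decidua had 1 higher and 1 lower of 14, over all genes and adjusted over the list alone (median 0.07; camera adjusted p = 0.677), the lower one being the alkaline phosphatase gene Alpl (-1.24, SE 0.21) and the higher one the growth factor gene Bmp2 (1.05). The Bmp2 call was lost in 5 of the 14 omissions of 1 library (edgeR adjusted p up to 0.0859, without PKO 1). Neutrophils had 0 higher and 1 lower of 9, over all genes and adjusted over the list alone (median -0.08; camera adjusted p = 0.438). That gene was the chemokine receptor gene Cxcr2 (-0.94), lost without PKO 1 (edgeR adjusted p = 0.0538).

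No member was called by edgeR at E14.5, over all genes or adjusted over the list alone, among 17 erythroid (median -0.06, camera adjusted p = 0.266), 16 macrophage (0.46, 0.599) and 9 NK and T cell genes (0.84, 0.969). This held too for 14 yolk sac and visceral endoderm genes (1.26, camera adjusted p = 0.268), 13 mitochondrially encoded transcripts (-0.06, 0.198) and 5 sex-linked transcripts (1.34, 0.690). The yolk sac genes, among them Afp, which encodes alpha-fetoprotein, varied together across libraries, with Afp from 52.3 CPM in the library labelled PKO 3 at E13.5 to 26427 CPM in PKO 2 at E14.5. Their mean level differed by 1.58 log2 units between PKO and control at E14.5 (SD 2.77 and 2.74, n = 4 each, two-sided exact permutation p = 0.429). With a covariate for this level, edgeR called 2340 genes at E14.5, and camera called 20 lists. Beside the same 17 these were parietal giant cells (median -0.52, adjusted p = 0.0453), cholesterol synthesis (-0.15, 0.0144) and mitochondrially encoded transcripts (-0.18, 0.0170).

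Cell cycle genes had 26 of 27 values above 0 in PKO at E14.5 and a median of 0.56, with 0 called over all genes and 0 adjusted over the list alone (camera adjusted p = 5.6e-05; adjusted p = 0.659 with an estimated correlation). Placental hormone genes had 4 lower and 0 higher of 14 (5 lower and 1 higher adjusted over the list alone; median -0.16; camera adjusted p = 0.0296; adjusted p = 0.357 with an estimated correlation). Camera lost that call without PKO 4 (adjusted p = 0.0541). The hormone median was -0.29 without control 1, -0.10 without control 3, -0.51 without PKO 2, -0.26 without PKO 3 and -0.38 with a covariate for yolk sac transcripts. Prl3b1, which encodes placental lactogen II, fell by 2.46 (SE 0.42), and the inhibin beta B gene Inhbb fell by 1.13 (SE 0.23). Nutrient transporters had 3 higher and 1 lower of 24 (5 higher and 1 lower adjusted over the list alone; median 0.04; camera adjusted p = 0.437). Imprinted genes had 3 higher and 1 lower of 22 (4 higher and 1 lower adjusted over the list alone; median 0.25; camera adjusted p = 0.283). The lower gene in both was Slc38a4, an amino acid transporter (-0.87, SE 0.18). Among the higher ones were the fatty acid carrier gene Cd36 (0.69) and the imprinted gene Dlk1 (0.60), both with overlapping groups and lost in 10 and 12 of the 14 omissions of 1 library (edgeR adjusted p up to 0.113 without PKO 4 and 0.116 without PKO 2). Hypoxia and glycolysis had 1 higher and 1 lower of 20 (3 higher and 2 lower adjusted over the list alone; median 0.27; camera adjusted p = 0.379). Cholesterol synthesis had 0 higher and 1 lower of 20, over all genes and adjusted over the list alone (median 0.08; camera adjusted p = 0.266), namely the lipoprotein receptor gene Ldlr (-1.23, SE 0.24). Among 3 tested adenosine deaminase genes, Adad2, a testis-enriched relative of Adar, was lower (-3.24), also adjusted over the list alone, from 0.426 ± 0.129 to 0.0414 ± 0.0354 CPM (n = 4 each; list median 0.02 where the test was lower; camera adjusted p = 0.344). Its call was lost without PKO 1 (edgeR adjusted p = 0.0525).

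**Figure D3:**
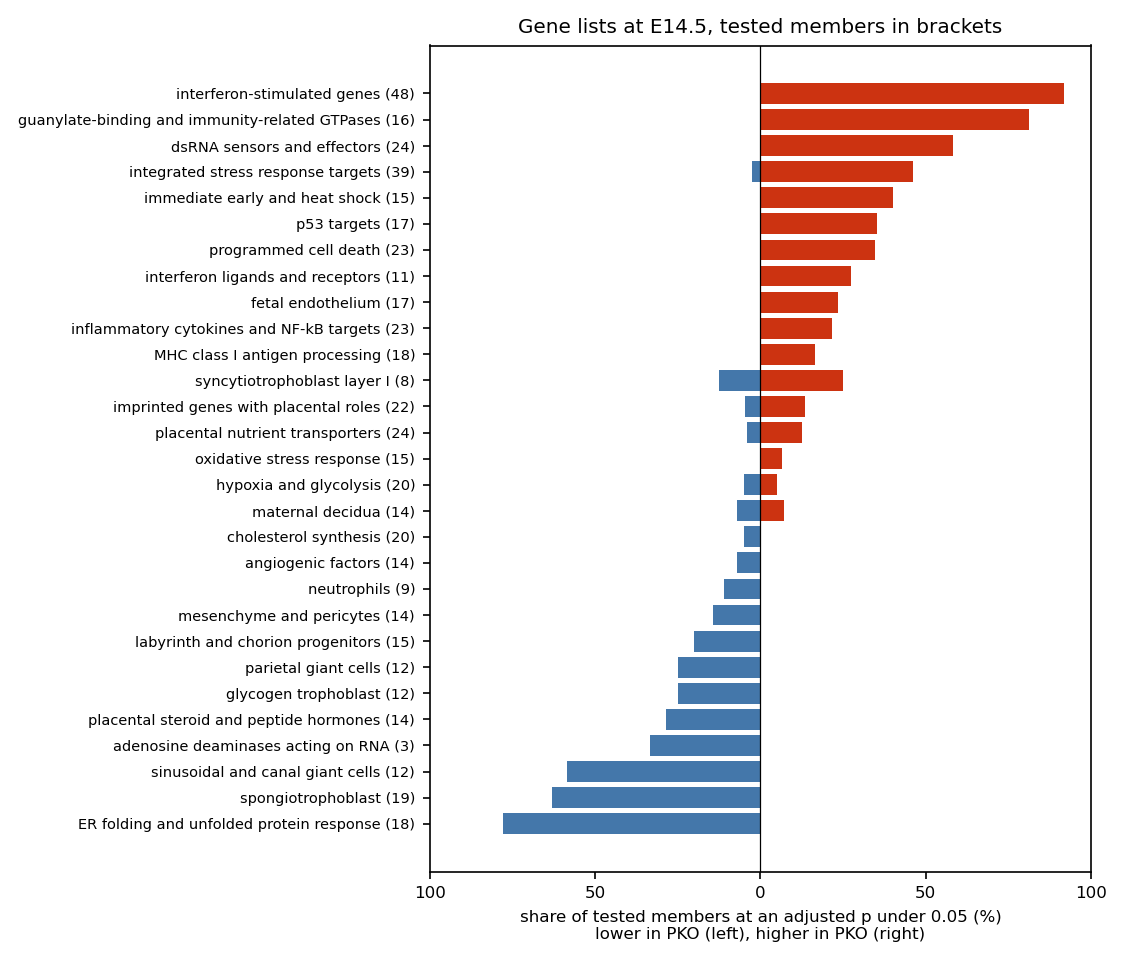
Share (%) of each fixed list's tested members that edgeR called higher (right) or lower (left) in PKO at E14.5, for the lists with at least 1 call; the number of tested members is in brackets. Interferon-stimulated genes (44 of 48 higher) and ER folding genes (14 of 18 lower) lie at the ends.

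At E13.5 the same question was asked 1 day earlier, and 2 of the 3 PKO libraries resembled those of E14.5 while 1 did not. On the interferon-stimulated list the PKO libraries labelled 1 and 2 lay 1.93 and 1.85 log2 units above the control mean, and the library labelled PKO 3 lay 0.15 below it. Mx2 was at 135.1, 100.1 and 2.96 CPM in PKO libraries 1, 2 and 3 and at 6.48 ± 4.81 CPM in controls (n = 3). Trib3 was at 104, 123 and 16.8 CPM in these libraries and at 11.9 ± 1.34 CPM in controls. Tpbpa was at 2281, 905 and 15294 CPM and at 12352 ± 2402 CPM in controls.

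By edgeR, 0 of 19504 genes passed at E13.5 with all 6 libraries, with 1052 at an unadjusted p under 0.05 and a smallest adjusted p of 0.614. DESeq2 called 55 genes, all higher in PKO. On simulated data of this size with 200 changed genes it made 61 false calls, 31.1% of its calls there. The number of truly changed genes is not known here, so the simulation cannot say how many of the 55 are false. Without the library labelled PKO 3, edgeR called 799 genes, 375 higher and 424 lower. In that fit Mx2 was higher by 4.18 (edgeR adjusted p = 8.0e-04), Trib3 by 3.26 (edgeR adjusted p = 1.8e-05) and the stress response gene Asns by 1.52 (edgeR adjusted p = 0.00251). Tpbpa was at -2.95 (edgeR adjusted p = 0.00382), Prl8a8 at -3.26 (edgeR adjusted p = 0.00727) and Calr at -1.08 (edgeR adjusted p = 0.0126). The library was singled out by such genes, so the fit without it is not an independent test of them.

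Ifnb1 had 24 and 36 counts in PKO libraries 1 and 2 at E13.5 and 0 in the library labelled PKO 3 and in the 3 controls. Ifnl2 had 26, 38 and 1 counts and Ifnl3 13, 45 and 0 counts in PKO libraries 1, 2 and 3, with 0 in the controls. Over the group, Ifnb1 was at least 19.4-fold, Ifnl2 at least 21.1-fold and Ifnl3 at least 18.8-fold higher than a floor of 3 counts.

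Among the fixed lists at E13.5, 43 of 48 interferon-stimulated genes were higher adjusted over the list alone, with 0 over all genes and a median of 1.24 (camera adjusted p = 3.7e-35; adjusted p = 0.317 with an estimated correlation). Guanylate-binding and immunity-related GTPases had 14 of 16 higher adjusted over the list alone (median 1.49; camera adjusted p = 7.5e-18; adjusted p = 0.253 with an estimated correlation). Integrated stress response targets had 20 of 39 higher adjusted over the list alone (median 0.63, 0.39 without PKO 2; camera adjusted p = 5.2e-20; adjusted p = 0.253 with an estimated correlation). Sensors and effectors of double-stranded RNA had 12 of 24 higher adjusted over the list alone (median 0.76, 0.41 without PKO 1; camera adjusted p = 2.5e-07; adjusted p = 0.331 with an estimated correlation). Adjusted over the list alone, 4 inflammatory, 4 cell death, 5 p53, 5 immediate early, 2 interferon and 1 oxidative stress genes were higher, each list also called higher by camera (estimated-correlation adjusted p of 0.331 to 0.470).

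Camera also called 2 lists higher at E13.5 without a member called, MHC class I (median 0.51, 0.19 without control 1 and 0.86 without control 2; adjusted p = 0.331 with an estimated correlation) and macrophages (0.43, 0.28 without control 1, 0.01 without PKO 2 and 0.72 without PKO 3; adjusted p = 0.695 with an estimated correlation). It called 4 lists lower, with 0 members called: spongiotrophoblast (-0.68), sinusoidal and canal giant cells (-0.43), ER folding (-0.42) and mitochondrially encoded transcripts (-0.25). With an estimated correlation their adjusted p values were 0.331, 0.411, 0.469 and 0.470. Without the library labelled PKO 3 the first 3 of these lists fell further, spongiotrophoblast to -2.03 with 12 members called lower by edgeR over all genes, sinusoidal giant cells to -1.07 with 2 and ER folding to -0.88 with 12. Their medians were -0.29, -0.26 and -0.21 without PKO 1 and -0.19, -0.16 and -0.17 without PKO 2, and that of spongiotrophoblast was -1.19 with a covariate for yolk sac transcripts, under which camera called erythroid cells as well (median 0.34, adjusted p = 0.0351). Camera lost the interferon ligand, oxidative stress and macrophage lists without control 1 (adjusted p = 0.107, 0.0597 and 0.606) or PKO 2 (0.157, 0.741 and 0.975), and sinusoidal giant cells without PKO 1 (0.0658). Without the library labelled PKO 3, 4 lists passed with an estimated correlation (camera adjusted p = 0.00238, 0.0198, 0.0132 and 0.00741). These were interferon-stimulated genes, double-stranded RNA sensors, stress response targets and GTPases. The library was singled out by such genes after the data were seen, so the fit without it is not an independent test of these lists. The yolk sac level of that library was the lowest of the 14, with Afp at 52.3 CPM against 11354 and 19323 CPM in PKO libraries 1 and 2, and the yolk sac list's median of 1.06 had the opposite sign to its test (camera adjusted p = 0.632).

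The difference between the PKO effects of the 2 stages asked whether the response changed from E13.5 to E14.5. Spongiotrophoblast genes differed by a median log2 difference of -2.24, with 12 of 19 more negative at E14.5 adjusted over the list alone. ER folding genes differed by -0.77, with all 18 values below 0, and interferon-stimulated genes by 0.35. By edgeR, 0 of 19504 genes passed, with 864 at an unadjusted p under 0.05, and DESeq2 also called 0. Camera called 11 of the 37 lists (17 without PKO 2 of E13.5), and 0 of them passed with an estimated correlation (adjusted p of 0.575 to 0.780). Without the library labelled PKO 3, the medians were -0.84 for spongiotrophoblast, -0.25 for ER folding and -0.01 for interferon-stimulated genes, the last no longer called (camera adjusted p = 0.467). In that fit, neutrophil genes (-0.93) and sex-linked transcripts (7.63) differed by more than spongiotrophoblast genes. The Y-linked gene Ddx3y had 1 count each in PKO 1 and 2 of E13.5 and 1678 in PKO 3. At E14.5, Ddx3y had 2089 and 2055 counts in PKO 1 and 4. The sex-linked value thus follows the unequal mix of sexes among the libraries and says nothing about the knockout. Interferon-stimulated genes differed by 0.60 without PKO 1 of E13.5. With a covariate for yolk sac transcripts, spongiotrophoblast differed by -1.47, ER folding by -0.43 and parietal giant cells by -0.27 (from -0.54), and cholesterol synthesis was called too (-0.30, camera adjusted p = 5.9e-05).

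The comparison of control placentas at E14.5 with those at E13.5 gave the background change between the stages, which cannot be separated from litter or day of sampling. Cell cycle genes were lower at E14.5, with 25 of 27 lower adjusted over the list alone, a median of -1.36 and 26 values below 0 (camera adjusted p = 3.1e-26; adjusted p = 0.753 with an estimated correlation). Maternal decidua genes had 13 of 14 values above 0 (median 0.96; camera adjusted p = 0.00109; adjusted p = 0.753 with an estimated correlation), and spongiotrophoblast genes 16 of 19 (median 0.62; camera adjusted p = 0.00547; adjusted p = 0.753 with an estimated correlation). Camera lost the decidua list without control 1 of E13.5 (adjusted p = 0.225), and in all called 17 lists, 11 without that library. The decidua median was 0.51 without it and 0.49 without control 4 of E14.5. The yolk sac list was itself among the 17 (camera adjusted p = 0.0113; adjusted p = 0.753 with an estimated correlation), and lost its call without control 1 or 4 of E14.5 (0.0762 and 0.0722). With a covariate for yolk sac transcripts, 7 of the 17 lists lost their call, among them spongiotrophoblast (median 0.32, camera adjusted p = 0.308), and interferon-stimulated genes (0.43, 8.0e-06) and macrophages (0.44, 0.00172) were called in addition. By edgeR, 0 of 19504 genes passed, with 2139 at an unadjusted p under 0.05 and a smallest adjusted p of 0.115. DESeq2 called 349 genes, 56 higher and 293 lower at E14.5.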

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

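Chosen after the results were seen were all tests of the library labelled PKO 3 and of the spongiotrophoblast fall and the scaling test of the ER folding genes, while the correlation of ER folding with spongiotrophoblast scores among controls was planned.

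The library labelled PKO 3 at E13.5 lacked the change of PKO 1 and 2. On most measures it lay among the controls or past them on the other side. Over 1883 genes called at E14.5 with a mean of at least 5 CPM, its change against the E13.5 controls correlated with the E14.5 effect at r = -0.640, against 0.922 and 0.940 for PKO 1 and 2 and -0.417 to 0.520 for each control against the other 2 (across genes, which are not independent replicates). An exchange of labels with an E13.5 control is argued against, because the highest control lay at 0.0246 on a scale of interferon-stimulated gene scores from 0 (mean of the controls) to 1 (mean of PKO 1 and 2), where PKO 3 lay at -0.0789 and the lowest control at -0.0326. On this scale PKO 3 lay at -0.322 for ER folding (lowest control -0.108) and -0.212 for spongiotrophoblast (-0.162). Each control is part of the mean it is measured against, which draws the control positions toward 0. The small gap for spongiotrophoblast thus does not place PKO 3 outside the controls. Partial admixture of tissue without the change, with the library at 0.1 to 0.9 of the way, is argued against as well. Over 274 genes with a mean of at least 5 CPM and a log2 fold change of at least 1 either way, called at E14.5 and moved the same way in PKO 1 and 2, the median position of PKO 3 was -0.229 (quartiles -0.483 and -0.0315; controls -0.117 to 0.233). It was -0.0277 over the 111 higher and -0.423 over the 163 lower genes. The integrated stress response score, at 0.113 (highest control 0.0613), was an exception, and that of GTPases, at 0.0600, lay within the controls (-0.0988 to 0.127). A placenta in which Adar1 was not deleted and a wrong genotype label were treated as 1 explanation, which could not be decided. Total Adar counts cannot test it, since they did not part the genotypes (log2 fold change 0.071 at E14.5). A biological difference between placentas of this genotype stays open and was not tested.

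Spongiotrophoblast genes fell at E14.5 by a median log2 fold change of -2.90. Dilution by more of a tissue other than labyrinth would lower the labyrinth lists alike. It is argued against by the syncytiotrophoblast and labyrinth progenitor lists, whose 31 genes had a median of 0.34 (quartiles -0.17 and 0.56). More labyrinth in the PKO pieces would not lower these lists, so the values cannot speak against it and it stays open. Yolk sac transcripts as the cause are argued against by the median of -2.59 with a covariate for them. Less of the whole junctional zone in the PKO pieces stays open: the spongiotrophoblast minus glycogen trophoblast score was lower in PKO by a difference of -2.08 (n = 4 each, two-sided exact permutation p = 0.0286), with all 4 PKO libraries below all 4 controls, yet 3 glycogen trophoblast genes were called lower. Fewer spongiotrophoblast cells and less transcript per cell are biological alternatives that total RNA leaves untested.

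ER folding genes fell at E14.5 by a median of -1.16 while 18 of 39 integrated stress response targets were called higher, and neither list passed with an estimated correlation (adjusted p = 0.328 and 0.373). Scaling of the libraries is argued against as the cause of the fall relative to other genes: a scale factor moves all genes alike, while the median of this list lay -1.23 from that of all tested genes (quartiles of its members -1.47 and -0.65). Amounts per cell were not measured. A candidate explanation is that the loss of spongiotrophoblast transcripts carries the fall, because among the 7 controls, each less its stage mean, the ER folding and spongiotrophoblast scores correlated (Pearson r = 0.890, two-sided exact permutation p = 0.00675; Spearman rho = 0.750, exact permutation p = 0.0663; 1 relation tested). Their slope of 0.58 (0.24 to 0.92) gives a change of -1.43 for the spongiotrophoblast change in PKO, against an observed -1.01. Without the 2 controls farthest from the median, r was 0.657. The controls spanned -0.42 to 0.30 on the spongiotrophoblast score, so the slope was extended beyond them to a PKO change of -2.49. ER folding was lowest in control 2 of E14.5 (-0.31) and highest in control 4 (0.25). There the yolk sac score was highest (3.75) and lowest (-2.31). The correlation cannot tell a link between the 2 lists from a shared dependence on yolk sac content. A direct effect on ER folding genes within cells was not tested.

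Single libraries at E14.5 stood apart from the others of their group in 10 of 226 values, where chance gives about 1 in 20 (by Dixon's test, the gap to the nearest library over the range of the group). Among controls, library 4 had 36.5 CPM of Prl3a1 against 32.7 to 33.3 (ratio 0.833) and 51.8 CPM of Tie1 against 67.3 to 69.7 (0.867). Control library 3 had 66.0 CPM of Hsd11b2 against 31.6 to 34.5 (0.915). PKO library 1 had 119 CPM of Mx2 against 86.4 to 90.6 (0.871) and 1214 CPM of Hspa5 against 1387 to 1423 (0.8294). PKO library 2 had a mean log2 CPM of nutrient transporters of 7.52 against 7.65 to 7.67 (0.913) and of cholesterol synthesis of 6.01 against 4.60 to 4.67 (0.949). It also had 4.99 CPM of Gdf15 against 2.65 to 3.04 (0.834) and 2.30 CPM of Eda2r against 3.75 to 3.96 (0.878). PKO library 4 had 0.548 CPM of Ifnb1 against 0.777 to 0.808 (0.880).

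The PKO effect differed between the stages by camera in 11 lists, 0 of them with an estimated correlation. Median log2 differences (E14.5 effect minus E13.5 effect) were above 0 for cell cycle (0.56), interferon-stimulated genes (0.35), dsRNA sensors (0.34), fetal endothelium (0.34) and syncytiotrophoblast layer II (0.28). They were below 0 for spongiotrophoblast (-2.24), sinusoidal and canal giant cells (-1.001), ER folding (-0.77), parietal giant cells (-0.54), erythroid cells (-0.49) and placental hormones (-0.30). With a covariate for yolk sac transcripts, parietal giant cells were at -0.27, ER folding at -0.43 and spongiotrophoblast at -1.47. Without the library labelled PKO 3, interferon-stimulated genes (-0.01, camera adjusted p = 0.467) and dsRNA sensors (0.15, camera adjusted p = 0.153) were no longer called and 9 of the 11 were, with medians of -0.84 for spongiotrophoblast, -0.46 for sinusoidal giant cells, -0.25 for ER folding and 0.29 for cell cycle. Camera called in addition, without PKO 3, integrated stress response targets (-0.17, adjusted p = 1.5e-05) and cholesterol synthesis (-0.15, 0.00215). The same held for macrophages (-0.26, 0.0310) and neutrophils (-0.93, 0.0416). With an estimated correlation the camera adjusted p of these lists was 0.364 to 0.755. The cell cycle median was 0.14 without control 1 and 0.88 without PKO 1 of E13.5, and that of interferon-stimulated genes 0.60 without PKO 1. Other single omissions ended the calls for fetal endothelium (6 libraries; camera adjusted p up to 0.574, without control 3 of E13.5), erythroid cells (3; up to 0.348, without PKO 2 of E13.5), parietal giant cells (2; up to 0.209, without PKO 2 of E13.5), syncytiotrophoblast layer II (2; up to 0.0890, without control 3 of E13.5) and hormones (1; 0.0654, without control 1 of E13.5). With 1 library left out, the median ranged from 0.12 (without control 3 of E13.5) to 0.43 (without control 2 of E13.5) for fetal endothelium, from 0.21 (without PKO 3 of E13.5) to 0.42 (without PKO 2 of E13.5) for syncytiotrophoblast layer II, from -0.82 (without PKO 1 of E13.5) to -0.43 (without PKO 3 of E13.5) for parietal giant cells, from -0.97 (without control 1 of E13.5) to 0.10 (without PKO 2 of E13.5) for erythroid cells and from -0.63 (without PKO 2 of E14.5) to -0.06 (without PKO 2 of E13.5) for hormones.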

How the results depend on the processing

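The covariate for yolk sac transcripts and the estimated correlation without the library labelled PKO 3 were chosen after seeing the data. No paired analysis was possible because the columns carry no code that links them to the sample titles, so the replicate block alternatives were not run, although the titles pair each PKO sample with a control. The count of 2566 genes at E14.5 stayed within 1.5 times under RLE scaling (2537), no filter (1735), a mean of at least 5 CPM (2265), DESeq2 (3643), limma on FPKM (2240 and 2248), the stage alone (3381) and covariates for Y-linked (3365) and yolk sac transcripts (2340). It was 989 with an absolute log2 fold change of at least 1, which by construction takes fewer genes, and 693 (without PKO 1) to 3545 (without PKO 3 of E13.5) with 1 library left out. Of 80 named genes called at E14.5, 37 stayed called in all 14 omissions. Kept and lost calls can lie close together: without PKO 1 the edgeR adjusted p was 0.0474 for Mx2 and Tpbpa and 0.0504 for Neurog2. The Adar log2 fold change at E14.5 turned in 3 of the 14 omissions, ranging from -0.0369 (without PKO 3) to 0.211 (without control 3). At E13.5, edgeR called 0 genes (1052 at an unadjusted p under 0.05), DESeq2 55, and 0 to 799 were called with 1 library left out, the latter without PKO 3, the library that lacked the change of PKO 1 and 2. The Adar log2 fold change at E13.5 ranged from -0.0993 (without control 3) to 0.195 (without control 2), and turned as well without PKO 1 (-0.0183) and PKO 3 (-0.0074). At E14.5 it turned without control 1 (-0.0078) and control 2 (-0.0041) too. Between stages in controls, edgeR called 0 genes (2139 at an unadjusted p under 0.05), DESeq2 349 and the Y-linked covariate 1, with 0 in all omissions. The difference between stages gave 0 genes under every alternative run. Of the 16 lists called at E13.5, 0 passed with an estimated correlation, 0 with fry and 4 with an estimated correlation without PKO 3. For the 17 at E14.5 these numbers were 0, 12 and 3, and for the 11 of the difference and the 17 between stages in controls 0, 0 and 0. With 1 library left out, 15 to 21, 15 to 20, 8 to 17 (without control 3 and PKO 2 of E13.5) and 11 to 20 lists were called (without control 1 and control 2 of E13.5). Macrophages at E13.5 turned in direction without PKO 2 (median 0.0139; 0.715 without PKO 3), and interferon-stimulated genes in the difference without PKO 3 (median -0.00757 with the preset and with an estimated correlation; 0.598 without PKO 1). Unless said, the cause was not tested. Depth leaves levels of up to 0.0868 to 0.0965 CPM open where a count is 0, and genes removed by the filter were not tested.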

Other observations

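The families and the yolk sac correlation below were examined after the data were seen, as were the splits for lists between stages in controls, while the other splits of the libraries were planned.

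Gene families defined by the start of their symbol (at least 10 tested members; 434 tests, one-sided Fisher's exact test, Benjamini-Hochberg) held groups of changed genes at E14.5. Members of several families, among them Prl, Psg, Ceacam, Gbp and Ifi, also stand in the fixed lists. The test takes genes as independent, while related genes can vary together across the same libraries. The p-values of the families thus do not measure the spread between placentas. Pregnancy-specific glycoprotein genes (Psg) were lower in 12 of 13 (median -3.55, adjusted p = 4.7e-11), Prl genes in 13 of 25 (-1.63, 2.1e-07) and Ceacam genes in 7 of 13 (-2.28, 0.000419), with reads that copies can share. Genes whose symbol starts with Sec, most of which serve protein transport through the ER, were lower in 15 of 29 (median -0.34, adjusted p = 1.8e-08), among them Sec24d (-1.24), Sec11c (-1.27) and Sec61b (-0.83). Without control 4, 1 Sec gene was called lower. Host genes of small nucleolar RNAs (Snhg) were higher in 8 of 15 (median 0.67, adjusted p = 7.1e-05), among them Snhg15 (2.00), Snhg16 (1.33), Snhg12 (1.28) and Snhg1 (1.28), and 4 were called without PKO 1. Ifi genes were higher in 10 of 17 (1.19, 1.5e-06; 3 without control 1), Gbp genes in 8 of 11 (1.501, 3.2e-06; 4 without control 1) and Trim genes in 17 of 59 (0.28, 6.7e-06; 4 without PKO 1). Parp genes were higher in 5 of 12 (0.33, 0.0274), among them Parp14 (1.68) and Parp10 (1.65).

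Yolk sac transcripts followed the first principal component of the 14 libraries, which held 38.2% of the variance. The score of the 14 yolk sac genes correlated with it at Pearson r = -0.912 (two-sided permutation p = 2.0e-05) and Spearman rho = -0.934 (permutation p = 1.0e-05, the smallest that 100000 permutations can give), and at r = -0.870 without the 2 libraries farthest from the median. It was 1 relation tested, over libraries of 4 groups.

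Other splits of the libraries into groups of the same sizes were compared with the real ones. At E14.5, 1 of 35 splits, the real one, gave as many genes, with 2566 against at most 2 in the others. This is the smallest share that 35 splits can give. Every other split mixes PKO and control libraries in both groups, which widens the spread within groups and lowers the count of genes. The size of the gap is thus partly built in. For lists at E14.5 chance could not be excluded (17 real, highest other 21; 5 of 35 splits gave as many), nor for lists between stages in controls (17, highest other 19; 5 of 35) or the difference (11, highest other 21; 76 of 100). For genes in the difference (0 real, highest other 1) and between stages in controls (0 real, highest other 1) the splits decide nothing, since any split gives at least 0 genes (100 of 100 drawn and 35 of 35). At E13.5 the 10 splits are too few for a share under 0.05 (genes: 0 real, highest other 1127; lists: 16 real, highest other 19, with 4 splits as large). The split with 1127 genes set control 1, PKO 1 and PKO 2 against control 2, control 3 and PKO 3, which points to a structure of the samples. The yolk sac score parted the same libraries, at 8.10, 8.70 and 9.11 against 6.87, 6.90 and 2.21 (mean log2 CPM). Whether it underlies the split was not tested. Against the mean of the other 2 controls, control 1 changed over the 1883 genes called at E14.5 with a correlation of r = 0.520 to the E14.5 effect (across genes), and controls 2 and 3 with r = -0.373 and -0.417. On the interferon-stimulated list, control 1 lay 0.02 log2 units above the control mean of its stage.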
